A study of Oryza sativa with 26 samples.

How the data were processed

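Gene expression was measured in the lamina joint of rice (Oryza sativa, japonica cultivar Zhonghua 11), the hinge between leaf blade and leaf sheath whose growth sets the leaf angle. Per the labels, the plants grew in a greenhouse, and lamina joints of the last leaf, of the second leaf counted back from it and of the third were cut by hand into liquid nitrogen at stages 2, 4, 5 and 6. They are called the last, the second and the third joint. A piece of the third leaf next to its joint was taken at stage 4 as a leaf control. Each of the 13 groups has 2 arrays, 26 in all, and the labels call these biological replicates without saying whether they came from separate plants or plots. The p-values measure only the spread between these samples. Total RNA was labelled with biotin and hybridised to 1-colour Affymetrix rice genome arrays, per the labels' protocols. The deposited values are log2 expression values per probe set, which the authors normalised with RMA, per the submitters' processing notes. The version of RMA, its background setting and the chip definition file are not given in the sources used here.

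The deposited log2 values run from 2.27 to 14.8, and array medians lie between 5.07 and 5.17, so no further scaling was applied. No value was missing, and 0.0419% of values were identical between the arrays of a group, so no pair was treated as 1 array deposited again. The table holds 57381 probe sets. The 123 control probe sets were left out of the tests and 57258 were tested. Gene names came from the platform annotation and from the RefSeq gene table of assembly ASM3414082v1 supplied for rice. By these, 22436 tested probe sets match 1 gene, 95 match several and 34727 match none, which means unnamed here. The matched probe sets represent 17905 genes, of which 2457 carry a descriptive name and 15448 only a locus identifier. A gene with several probe sets was represented in lists and names by the probe set with the highest mean over all arrays. No genome was supplied, so no coordinates are given.

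All 26 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3) with a mean for each of the 13 groups and no block, which leaves 13 residual degrees of freedom. The moderated variances had 3.52 prior degrees of freedom and a prior SD of 0.206. The contrasts were joint against leaf in the third leaf at stage 4, the 3 stage steps averaged over the 3 leaf positions, and the 3 pairs of leaf positions averaged over the 4 stages. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested and at least a 2-fold difference. limma's tests are two-sided. The same steps were also taken within each leaf position. A limma F-test over 6 contrasts asked whether any step differed between positions, at an adjusted p under 0.05 with no fold limit. The root-mean-square log2 difference between group means compared pairs of joints of the same stage with pairs of the same day after sowing, by a one-sided exact permutation test that relabelled the stages within leaf positions. Principal components were taken from the centred log2 values.

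Gene lists were tested with camera, limma's competitive test, at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data and with fry. Adjusted p-values of list tests are over the lists of a comparison. The themes and patterns of 37 lists were fixed before the data were examined, but those patterns addressed gene titles and the supplied tables hold symbols only. Membership was therefore rewritten as symbol patterns after the annotation tables had been read and before any list result was computed. The cell cycle list holds 8 cyclin and cyclin-dependent kinase genes and 18 kinesins. Lists needed at least 4 measured genes, and 30 were tested. The other 7 could not be tested: xyloglucan endotransglycosylases and phloem markers matched 1 gene each, carbon fixation and peroxidases 3 each, and pectin remodelling, proteases and xylem transcription factors 0. The fixed markers of other tissues that a hand-cut joint could hold were light-harvesting proteins for green leaf, cuticle and lipid-transfer genes for epidermis, KNOX genes for meristem and floral MADS genes for the panicle.

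Genes are named by a rule fixed before the data were examined, for joint against leaf, the 3 stage steps and the last against the third joint. It takes the 5 largest rises and 5 largest falls among called, named, single-gene probe sets that move the same way in every position or stage, then the 2 most changed called members of each list with a camera adjusted p under 0.05, and finally 24 genes of leaf angle, hormone signalling, flowering and senescence. Of these 24, 16 were matched. LC2, LPA1, ILI1, D2, DLT, ARF19, CYCU4;1 and NAP were not matched by name and are not analysed here. A few genes outside the rule are named where a list had few called members, and they were chosen after their values were seen.

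Arrays simulated from each probe set's mean over all arrays and fitted spread were run through the same code. With 100 of 57258 probe sets changed at each size, joint against leaf recovered 83% of log2 changes of 1.5 and 97% of changes of 3, with 9 false calls. The stage 4 to stage 5 step recovered 97% and 100%, with 0 false calls, and the last against the third joint recovered 99% and 100%, with 2 false calls. The F-test recovered 52% and 92% of changes made at stage 5 of the third joint alone, with 7 false calls.

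Alternatives fixed beforehand were a further quantile normalisation, centring each array on its median, leaving out probe sets whose mean over all arrays lies below the median of such means, 1 probe set per gene, limma's trend and robust options together, only the arrays compared, the replicate number as a block, no fold limit, limma's treat, and leaving out each array in turn. For lists they were also the mean of a gene's probe sets, an estimated correlation and fry. Added after seeing the data were the Gapdh 3′ minus 5′ difference as a covariate, leaving out the arrays of the second joint at stage 5 replicate 1 and the third joint at stage 4 replicate 2, and all alternatives for steps within a position and for correlations of steps.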

Results

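Lamina joints of rice were profiled on 26 arrays in 13 groups of 2. The last joint was taken 60, 65, 70 and 80 days after sowing at stages 2, 4, 5 and 6. The second joint was taken at 55, 60, 65 and 75 days and the third joint at 50, 55, 60 and 70 days. Per the labels, joints were young and white or creamy at stage 2, mature with a leaf angle of 0 at stage 4, opening at stage 5 and senescent and dehydrated at stage 6. A green piece of the third leaf served as leaf control at stage 4. Values are log2 expression per probe set, and the number of arrays limits their precision. Array medians lay between 5.07 and 5.17. The upper quartile was 7.50 in the second joint at stage 5 replicate 1 and 7.90 to 8.07 on the other arrays. Replicates correlated across genes at r from 0.971 to 0.995, with genes not being independent replicates.

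The 3′ probe set of the Gapdh control exceeded its 5′ probe set by 2.93 to 3.78 on 9 arrays and by 1.47 to 2.09 on the other 17. The 9 arrays were both arrays of the last joint at stage 5, all 6 arrays of stage 6 and the third joint at stage 4 replicate 2, which had the highest value of 3.78. The leaf arrays had 1.78 and 1.82.

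**Figure D1:**
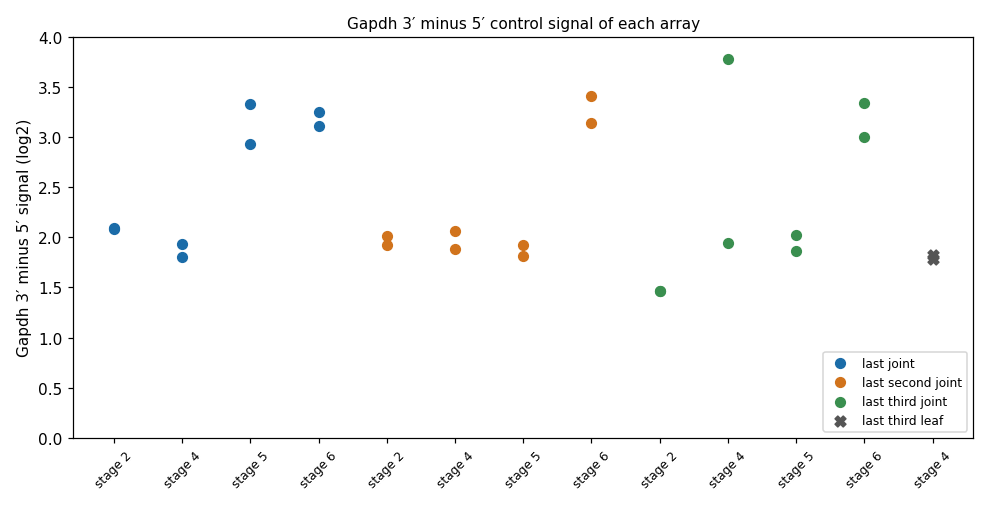
Difference between the 3′ and 5′ Gapdh control probe sets (log2, vertical axis) for each of the 26 arrays, 1 point per array, by leaf position and stage. All 6 arrays of stage 6 lie above 3, and the third joint at stage 4 has 1 array at 1.95 and 1 at 3.78.

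Stage set the arrays apart more than leaf position. The first principal component held 49.7% of the variance and placed the stage 2 joints between -215.7 and -124.5, the stage 4 joints between 5.77 and 27.6, stage 5 between 28.7 and 74.8 and stage 6 between 70.1 and 90.9. The second component held 12.9% and placed the leaf arrays at 130.1 and 127.7, with every joint array at 56.5 or below. EXPA1, an expansin that loosens the cell wall, followed the stages, from 13.1 to 13.2 in the joints at stage 2 to 11.1 to 11.2 at stage 4, 9.02 to 9.57 at stage 5 and 5.93 to 8.33 at stage 6. LG1, required to form the ligule, auricle and joint, stayed between 8.15 and 9.58 in the 12 joint groups and was 5.93 in the leaf. Averaged over all pairs, joints of different leaves were closer at the same stage than on the same day. Their root-mean-square log2 distance was 0.455 over 12 pairs of the same stage (range 0.284 to 0.681) and 0.577 over 6 pairs of the same day (0.324 to 0.875), against 0.791 over the other 30 pairs. A one-sided exact permutation test gave p = 0.00521, with 3 of 576 relabellings of stages giving a same-stage distance as small. That test compares with relabelled stages and not with pairs of the same day. The 3 pairs of the same day that include stage 2 lay 0.706, 0.824 and 0.875 apart. The other 3 lay 0.393, 0.338 and 0.324 apart, against means of 0.412, 0.461 and 0.368 for pairs of the same stage at stages 4, 5 and 6, so that from stage 4 on the order is not the same.

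**Figure D2:**
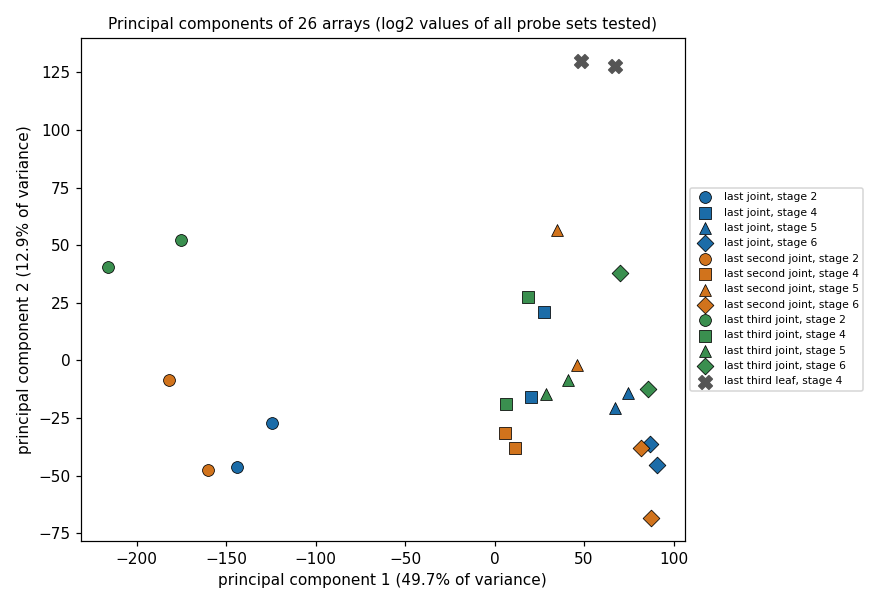
Scores of the 26 arrays on the first (49.7% of variance, horizontal) and second (12.9%, vertical) principal components of the log2 values, 1 point per array, with colour for leaf position and shape for stage. Stage 2 joints lie at -124.5 or below on the first component, and the 2 leaf arrays lie at 130.1 and 127.7 on the second.

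The joint of the third leaf was compared with the leaf piece beside it at stage 4, to find the genes that set the joint apart from the leaf. Of 57258 probe sets, 4243 were called, 1957 higher and 2286 lower in the joint (46.1% higher). This balance turns with only the 4 arrays compared (60.2% higher), with 1 probe set per gene (54.5%) and with treat, a stricter test of the fold limit (59.5%). Light-harvesting and photosystem genes were lower, with 5 of 7 called lower, 0 higher and 2 not called. Adjusted over the list alone, 6 were lower. Their median log2 difference was -1.71 (camera adjusted p = 4.88e-05; adjusted p = 0.217 with an estimated correlation). The chlorophyll a/b-binding proteins RCABP89 and RCABP69 differed by -3.20 (SE 0.598, limma adjusted p = 0.0018) and -3.04 (SE 0.412, adjusted p = 0.000114). Cellulose synthases of the primary wall were higher in the joint, 4 of 5 called higher and 5 adjusted over the list alone, with a median of 1.78 (camera adjusted p = 0.00103; adjusted p = 0.238 with an estimated correlation). CESA6 was higher by 2.08 (SE 0.273, adjusted p = 8.52e-05) and CESA1 by 1.89 (SE 0.432, adjusted p = 0.00828). All 4 genes of secondary wall cellulose were called higher, also adjusted over the list alone, with a median of 1.59 (camera adjusted p = 0.00223; adjusted p = 0.257 with an estimated correlation). They include CESA4 at 2.29 (SE 0.296, adjusted p = 7.39e-05) and the COBRA-like BC1 (LOC4333114) at 1.68 (SE 0.407, adjusted p = 0.0122). Of 10 tubulins, 4 were called higher and 7 adjusted over the list alone, with a median of 1.15 (camera adjusted p = 0.00402; adjusted p = 0.332 with an estimated correlation). TUB1 at 2.25 and TUB6 at 1.65 differed most. Of 29 expansins, 8 were called higher, 0 lower and 21 not called, and 9 were higher and 1 lower adjusted over the list alone. Their median was 0.31 (camera adjusted p = 0.0192; adjusted p = 0.257 with an estimated correlation), with EXPA1 at 5.75 (SE 0.496, adjusted p = 1.23e-06) and EXPA6 at 4.03 (SE 0.309, adjusted p = 4.09e-07). Without the third joint replicate 1, the calls of the expansin list (adjusted p = 0.173), CESA1 (1.66, adjusted p = 0.0854) and BC1 (1.35, adjusted p = 0.139) were lost. Without leaf replicate 2 the same 3 calls were lost (adjusted p = 0.176, 0.16 and 0.192). CESA1 was then at 1.13, BC1 at 1.11, and the mean of the primary wall list was 1.07 in place of 1.68. With only these 4 arrays in the fit, CESA1, BC1, TUB1 and TUB6 had adjusted p from 0.0891 to 0.146, and with the Gapdh difference as a covariate TUB6 had 0.0712.

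Auxin genes other than Aux/IAA repressors were higher on balance in the joint, 7 of 32 called higher and 1 lower, with the same counts adjusted over the list alone and a median of 0.46 (camera adjusted p = 0.00153; adjusted p = 0.227 with an estimated correlation). GH3.4 and GH3.8, which conjugate auxin to amino acids, were higher by 3.49 (SE 0.544, adjusted p = 0.000404) and 3.16 (SE 0.683, adjusted p = 0.00547). Of 9 gibberellin genes 4 were called higher and 0 lower, also adjusted over the list alone, with a median of 0.96 (camera adjusted p = 0.037; adjusted p = 0.217 with an estimated correlation). The synthesis genes KAO at 2.57 and D35 at 1.58 are among them. Of 22 growth-regulating factor and SPL genes 6 were called higher and 0 lower, also adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.0101; adjusted p = 0.217 with an estimated correlation). GRF4 was higher by 4.56 (SE 0.374, adjusted p = 7.56e-07), GRF3 by 3.48 (SE 0.304, adjusted p = 1.39e-06) and LG1 by 3.01 (SE 0.493, adjusted p = 0.000608). LA, which acts in shoot gravitropism and tiller angle, was higher by 5.88 (SE 0.254, adjusted p = 9.44e-10). Of the brassinosteroid regulators, BU1 was higher by 2.34 and the transcription factor BZR1 by 1.10, and IBH1, which opposes growth in that pathway, differed by -1.69 (adjusted p = 0.00636, 0.00431 and 0.00469). The DELLA protein gene SLR1 was higher by 1.04 (adjusted p = 0.00862). The 10 brassinosteroid genes together had a median of 0.12 (2 higher, 1 lower; 2 and 2 adjusted over the list alone; camera adjusted p = 0.686). Not called were BRI1 at 0.45, D11 at -1.34, GSK2 at 0.15, LIC at -0.02, RGA1 at -0.15 and GH3.1 at -0.29. Without replicates 1 and 2 of the third joint BRI1 was at 0.76 and 0.15, D11 at -0.79 and -1.90, GSK2 at 0.69 and -0.39, LIC at 0.32 and -0.36 and RGA1 at -0.39 and 0.08, and without leaf replicates 1 and 2 GH3.1 was at -0.15 and -0.44, none called. Without the third joint replicate 1, GH3.8 (2.86, adjusted p = 0.0596), BU1 (1.99, adjusted p = 0.0804), BZR1 (0.96) and the gibberellin list (adjusted p = 0.104) lost their calls, and without its replicate 2 SLR1 did (0.99). Without leaf replicate 1, KAO (2.07, adjusted p = 0.051), D35 (1.26, adjusted p = 0.0538) and IBH1 (adjusted p = 0.0782) lost theirs. Without leaf replicate 2, GH3.8 (2.79, adjusted p = 0.0612), BU1 (2.04, adjusted p = 0.0697), BZR1 (just under 1), SLR1 (0.84) and the gibberellin list (adjusted p = 0.0793) lost theirs. With only these 4 arrays in the fit, the gibberellin list, KAO, D35, BZR1 and SLR1 had adjusted p from 0.0544 to 0.0892. With the Gapdh covariate KAO and D35 had 0.0553 and 0.0659, and SLR1 was at 0.85.

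The largest differences between joint and leaf were those of FOR1 (LOC4343645), a leucine-rich repeat floral organ regulator, at 6.11 (SE 0.489, adjusted p = 5.86e-07), LA and EXPA1 as above, the dehydrin RAB21 at 5.66 (SE 0.883, adjusted p = 0.000404) and ACO1, an enzyme of ethylene synthesis, at 5.18 (SE 0.504, adjusted p = 4.45e-06). In the other direction were PDX12 at -4.07, MADS57 at -3.37, the sugar transporter SWEET1B at -3.32, RCABP89 as above and the peroxiredoxin PRXIIE-2 at -3.16 (adjusted p = 0.00142). Of 8 dehydration genes 3 were called higher and 0 lower, also adjusted over the list alone, with a median of 1.53 (camera adjusted p = 0.0192; adjusted p = 0.421 with an estimated correlation). RAB21 and rDRP1 (2.17, adjusted p = 0.0244) are among them. Of 28 DNA replication genes 3 were called lower and 4 adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.00326; adjusted p = 0.421 with an estimated correlation). The helicase subunits MCM2 and MCM4 differed by -1.98 (adjusted p = 0.00308) and -1.78 (adjusted p = 0.0111). The 26 genes of the cell cycle list, 18 of them kinesins, had a median of 0.01 and a mean of 0.29, with 5 higher and 0 lower (camera adjusted p = 0.43). Among markers of other tissues, 1 of 6 cuticle and lipid-transfer genes was called higher, also adjusted over the list alone, with a median of 0.75 (camera adjusted p = 0.037; adjusted p = 0.217 with an estimated correlation), and that gene was LTPL1 at 1.10. Of 9 KNOX genes 2 were called higher, also adjusted over the list alone (median 0.06, mean 0.84; camera adjusted p = 0.43). They were OSH71 at 3.34 and HOS66 at 4.83, named after their values were seen. None of 8 floral MADS genes was called by limma, 2 having an unadjusted p under 0.05 (median -0.00368; camera adjusted p = 0.783). The flowering genes MADS14, MADS15 and MADS18 were at -0.69, -0.38 and 0.29, and the chlorophyll breakdown genes SGR and NYC1 at 0.44 and -0.62, none called. These values depend on single arrays: without replicates 1 and 2 of the third joint MADS14 was at -1.89 and 0.51, MADS15 at -1.84 and 1.08, MADS18 at -0.08 and 0.65 and NYC1 at -1.10 and -0.14, and without leaf replicates 1 and 2 SGR was at 0.91 and -0.04. Without the third joint replicate 1, the dehydration list (adjusted p = 0.204), the cuticle list (0.121), rDRP1 (1.47, 0.277) and MCM4 (-1.59, 0.0991) lost their calls. Without leaf replicate 1, the cuticle list (0.0501) and MCM4 (0.0672) did, and PRXIIE-2 was at -1.87. Without leaf replicate 2, the dehydration list (0.0705), the cuticle list (0.0701), rDRP1 (1.65, 0.228), MCM2 (-1.48, 0.0606), MCM4 (0.0566) and LTPL1 (0.79, 0.0553) did. The cuticle list also lost its call after a further quantile normalisation (0.0538) and, with the DNA replication list (0.069), without dim probe sets (0.0504). With only these 4 arrays, PRXIIE-2, MCM2, rDRP1 and LTPL1 had adjusted p from 0.057 to 0.134, and with the Gapdh covariate LTPL1 was just under the fold limit. The Gapdh difference was 1.95 and 3.78 in the joint arrays and 1.78 and 1.82 in the leaf.

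**Figure D3:**
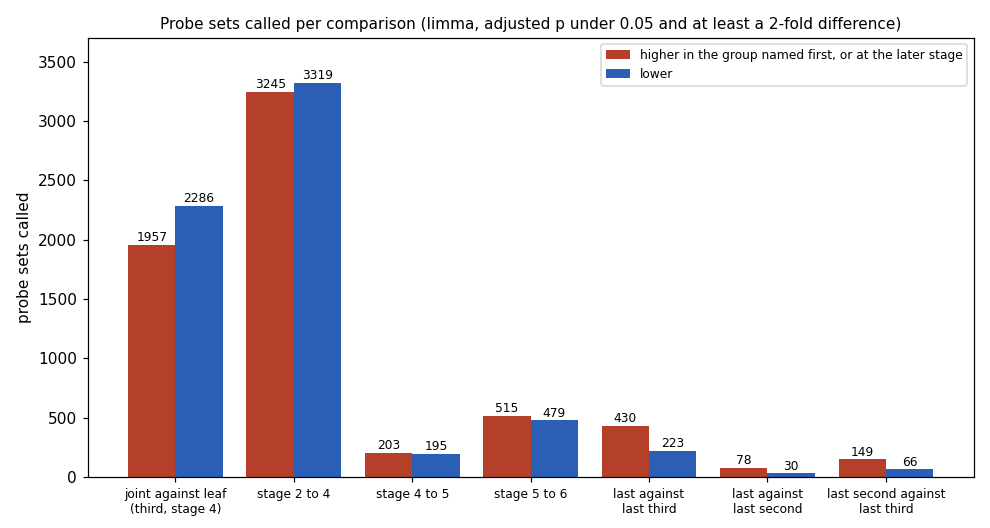
Number of probe sets called (vertical axis) higher (red) and lower (blue) in the group named first or at the later stage, for 7 comparisons (limma, adjusted p under 0.05 and at least a 2-fold difference). Stage 2 to stage 4 has the highest bars, 3245 and 3319, and the last against the second joint the lowest, 78 and 30.

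From stage 2 to stage 4, the young joint becoming mature, cyclin, kinesin and secondary wall cellulose genes fell on balance. With the 3 leaf positions averaged, 3245 probe sets rose and 3319 fell, 6564 of 57258. Of the 26 genes of the cell cycle list, 18 fell, 1 rose and 7 were not called. Of its 8 cyclin and cyclin-dependent kinase genes 6 fell (median -2.19), and of its 18 kinesins, motor proteins, 12 fell and 1 rose (median -1.12). The list had the same counts adjusted over the list alone and a median of -1.31 (camera adjusted p = 2.73e-06; adjusted p = 0.328 with an estimated correlation). The mitotic cyclin CYCB2-1 fell by 3.91 (SE 0.376, limma adjusted p = 3.96e-07) and the kinesin KIN12C at -3.72. All 4 genes of secondary wall cellulose fell, also adjusted over the list alone, with a median of -3.10 (camera adjusted p = 0.000203; adjusted p = 0.328 with an estimated correlation). CESA7 was at -3.23 (SE 0.146, adjusted p = 4.39e-11) and BC1 (LOC4333114) at -3.17. Of 29 expansins 12 fell and 1 rose, also adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.000308; adjusted p = 0.328 with an estimated correlation). EXPB11 was at -5.22 (SE 0.415, adjusted p = 4.02e-08) and EXLA4 at -3.73. Of 10 tubulins 3 fell and 0 rose, also adjusted over the list alone, with a median of -0.79 (camera adjusted p = 0.0081; adjusted p = 0.445 with an estimated correlation). TUB4 at -1.93 and TUB8 at -1.63 are among them. Of 29 lignin genes 6 fell and 0 rose, also adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.0225; adjusted p = 0.427 with an estimated correlation). 4CL2, of lignin synthesis, was at -5.06 (SE 0.298, adjusted p = 1.05e-09) and the laccase LAC10 at -4.71. The lignin list lost its call without the third joint at stage 4 replicate 2 (adjusted p = 0.0583), without that array and the second joint at stage 5 replicate 1 (0.0656), and with the Gapdh covariate (0.0727). The Gapdh difference was 1.47 to 2.09 at stage 2 and, apart from that array, 1.81 to 2.07 at stage 4.

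Chitinases and other defence genes rose over the same step, 9 of 15 called higher and 1 lower, with the same counts adjusted over the list alone and a median of 1.54 (camera adjusted p = 0.0202; adjusted p = 0.554 with an estimated correlation). Cht11 rose by 4.85 (SE 0.223, adjusted p = 5.25e-11) and Cht2/Cht8 by 4.72 (SE 0.242, adjusted p = 1.98e-10). Of 10 brassinosteroid genes 3 fell and 0 rose, also adjusted over the list alone, with a median of -0.55 (camera adjusted p = 0.0202; adjusted p = 0.427 with an estimated correlation). The brassinosteroid synthesis gene CYP85A1 fell by 2.59 (SE 0.243, adjusted p = 2.94e-07), and D11, of the same pathway, fell by 2.32 (SE 0.309, adjusted p = 1.5e-05). The largest rises were those of NAS3, a nicotianamine synthase, at 6.16 (SE 0.329, adjusted p = 3.34e-10), ASMT of the melatonin pathway at 5.11 (SE 0.478, adjusted p = 2.85e-07), the chitinases above and RDB1 at 4.64. The germin-like GER5 fell by 7.55 (SE 0.513, adjusted p = 6.06e-09), the endoglucanase GLU8 at -7.03 (SE 0.171, adjusted p = 5.03e-14), the lipid-transfer protein LTP110-A at -6.28, the cellulose synthase-like CSFL8 at -5.74 and GER8 at -5.69. NYC1, a chlorophyll b reductase, rose by 1.15 (SE 0.185, adjusted p = 0.000114), and by 0.99, under the 2-fold limit, without the third joint at stage 4 replicate 1. MADS14 at 0.83 was not called, and was called without the second joint at stage 2 replicate 1 (1.14), without the third joint at stage 4 replicate 2 (1.23) and with the Gapdh covariate (1.29). BRI1 at -0.57 (adjusted p = 0.0228) and GH3.1 at -0.50 (adjusted p = 0.0356) passed the adjusted p and not the fold limit. LG1 at -0.18, BU1 at -0.19, IBH1 at -0.56, SLR1 at -0.37, MADS15 at 0.56 and SGR at 0.23 were not called. Leaving out 1 array moved MADS15 to between 0.07 and 1.04 (the third joint at stage 4 replicates 1 and 2), IBH1 to between -0.77 and -0.34 (the third joint at stage 2 replicates 2 and 1), SGR to between 0.11 and 0.34 (the same stage 2 arrays) and LG1 and BU1 to no less than -0.32 and -0.37. Lists without a camera call at this step include the light-harvesting genes (1 higher, 3 lower of 7, median -0.64, adjusted p = 0.266), the cuticle genes (1 higher, 3 lower of 6, median -0.58, adjusted p = 0.382), the KNOX genes (2 higher, 1 lower of 9, median -0.08) and the floral MADS genes (1 higher of 8, median -0.14, mean 0.01). In the last, the second and the third joint alone, 5201, 6221 and 8303 probe sets were called. Of the genes called by the naming rule at this step, 3 were not called in every joint alone: KIN12C in the last (-1.72, adjusted p = 0.121), and TUB8 (-0.44, adjusted p = 0.796) and D11 (-0.82, adjusted p = 0.395) in the second. Of the 6564, 6258 (95.3%) moved the same way in all 3 positions, which selection on their mean favours. Steps of separate positions, which share no arrays, correlated across genes at r from 0.647 to 0.764.

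**Figure D4:**
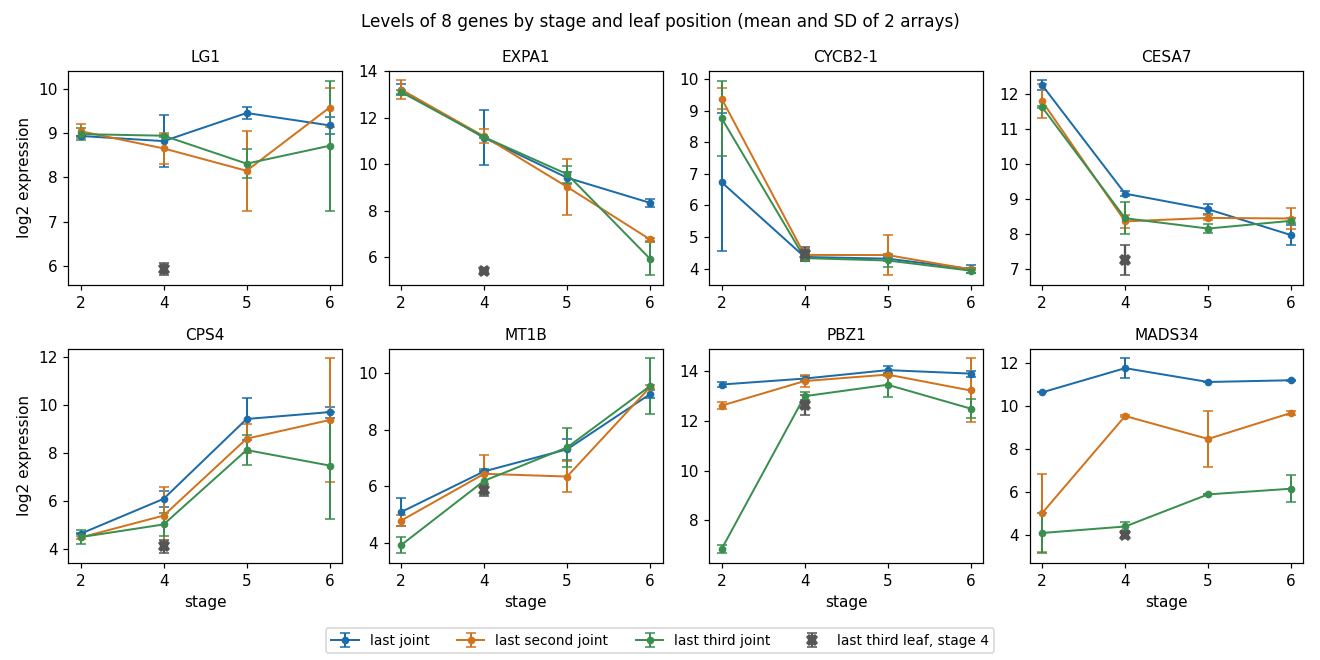
Level of 8 genes (log2, vertical axes) by stage (horizontal axes) in the last, the second and the third joint (lines) and in the leaf at stage 4 (grey crosses), as the mean of 2 arrays with its SD. EXPA1 lies at 13.1 to 13.2 at stage 2 and at 5.93 to 8.33 at stage 6, and PBZ1 at stage 2 lies at 6.84 in the third joint and at 12.6 and 13.5 in the other joints.

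From stage 4 to stage 5, when the leaf angle starts to open, 203 probe sets rose and 195 fell with the 3 positions averaged, 398 of 57258. The 5 largest rises by the naming rule were those of CPS4, KS3, KS4 and KS10, which encode diterpene synthases, and of CYP71Z7. No list of such genes was tested. CPS4 rose by 3.21 (SE 0.556, limma adjusted p = 0.00637), CYP71Z7 by 3.11 (SE 0.472, adjusted p = 0.00237) and KS3 by 2.35 (SE 0.402, adjusted p = 0.00597), and these 3 kept their calls whichever array was left out. KS10 at 3.24 (SE 0.733, adjusted p = 0.0376) and KS4 at 2.57 (SE 0.571, adjusted p = 0.0339) kept theirs only without the last joint at stage 5 replicate 1, the second joint at stage 4 replicate 1 or the second joint at stage 5 replicate 2. They reached adjusted p = 0.16 and 0.146 without the other arrays. Cht5 fell by 2.49 (SE 0.455, adjusted p = 0.00963) and BGLU30 fell by 2.25 (SE 0.393, adjusted p = 0.00687). RAB21 fell by 2.39 (adjusted p = 0.026). Its call was lost without either stage 4 array of the last joint, the last joint at stage 5 replicate 2, the second joint at stage 4 replicate 1, either stage 4 array of the third joint or the third joint at stage 5 replicate 2 (adjusted p up to 0.101). EXPA5 fell by 2.15 (adjusted p = 0.0343). Its call was kept only without the last joint at stage 4 replicate 1, the second joint at stage 5 replicate 2, the third joint at stage 4 replicate 2 or the third joint at stage 5 replicate 2 (adjusted p up to 0.139 without the others). IPS fell by 1.93 (adjusted p = 0.041), a call kept only without the second joint at stage 5 replicate 2 or the third joint at stage 4 replicate 2 (adjusted p up to 0.138). In single joints none of these 10 genes was called, apart from Cht5 and BGLU30 in the third (adjusted p = 0.0295 and 0.0454). With only the arrays compared, EXPA5 and IPS had adjusted p = 0.14 and 0.0609. With both doubtful arrays out, the second joint at stage 5 replicate 1 and the third joint at stage 4 replicate 2, KS10, KS4 and RAB21 had 0.107, 0.128 and 0.0844. The count of 398 was 243 without the last joint at stage 4 replicate 2, 256 without the second joint at stage 4 replicate 2, 243 without the third joint at stage 5 replicate 1 and 720, of which 33.8% higher in place of 51%, without the second joint at stage 5 replicate 2.

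The Aux/IAA repressors were the 1 list of 30 with a camera call at this step. None of the 26 was called by limma, over all probe sets or adjusted over the list alone, with 1 higher and 10 lower at an unadjusted p under 0.05 and a median of -0.20 (camera adjusted p = 0.0395; adjusted p = 0.138 with an estimated correlation). The list lost its call without the last joint at stage 4 replicate 1 (adjusted p = 0.168), the last joint at stage 5 replicate 2 (0.0513), the second joint at stage 4 replicate 1 (0.118), the second joint at stage 5 replicate 2 (0.317), or either stage 4 array of the third joint (0.0506 and 0.0692). It also lost it without dim probe sets (0.0886) and with the Gapdh covariate (0.0583). Of 29 expansins 2 fell and 0 rose (median -0.07, adjusted p = 0.412), and of 32 jasmonate genes 2 rose, 4 adjusted over the list alone (median -0.09, mean 0.01, adjusted p = 0.773). These were AOS2 at 1.27 (adjusted p = 0.02) and LOX8 at 2.05 (adjusted p = 0.032), named after their values were seen. In single joints AOS2 was not called, and LOX8 was called in the last alone, at 4.46 (adjusted p = 0.011), with 1.07 in the second and 0.62 in the third (interaction adjusted p = 0.108). AOS2 lost its call without the last joint at stage 4 replicate 2 or stage 5 replicate 1, the second joint at stage 4 replicate 2, or replicate 1 of the third joint at stage 4 or stage 5 (adjusted p up to 0.0908). LOX8 kept its call only without the second joint at stage 4 replicate 1, either stage 5 array of the second joint or the third joint at stage 5 replicate 2 (adjusted p up to 0.136 without the others). With only the arrays compared they had adjusted p = 0.127 and 0.159, and AOS2 had 0.0554 with both doubtful arrays out. The light-harvesting, KNOX and floral MADS lists had 0 genes called by limma, with 1, 2 and 2 at an unadjusted p under 0.05, and the cuticle list 1 of 6 lower (median -0.24, adjusted p = 0.142). No fixed gene of leaf angle, hormone signalling, flowering or senescence was called, among them BU1 at -1.07 (adjusted p = 0.112) and LG1 at -0.17. BU1 was called without the second joint at stage 5 replicate 2 (-1.33, adjusted p = 0.0127). Of the 398, 350 (87.9%) moved the same way in all 3 positions. Across all genes the steps of separate positions did not move together, with r = -0.00673 between the last and the second joint, 0.071 between the last and the third and -0.057 between the second and the third. These r ranged from -0.181 to 0.242 when arrays were left out in turn. Over this step the Gapdh difference rose from 1.87 to 3.13 in the last joint and fell from 2.86 to 1.94 in the third. The second had 1.87 at stage 5.

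From stage 5 to stage 6, the step to the senescent joint, 515 probe sets rose and 479 fell, 994 of 57258. Of 29 expansins 4 fell and 0 rose, with 4 lower and 1 higher adjusted over the list alone and a median of -0.14 (camera adjusted p = 0.000671; adjusted p = 0.174 with an estimated correlation). EXPA1 was at -2.33 (SE 0.286, limma adjusted p = 0.000188) and EXPB6 at -1.80 (SE 0.313, adjusted p = 0.00297). Of 26 Aux/IAA repressors 2 fell and 1 rose, with 3 lower and 1 higher adjusted over the list alone and a median of -0.21 (camera adjusted p = 0.000583; adjusted p = 0.0136 with an estimated correlation). IAA30 was at -1.70 (SE 0.19, adjusted p = 9.4e-05) and IAA12 at -1.51 (SE 0.208, adjusted p = 0.000523). The riser was IAA6 at 1.32, named after its value was seen and not called with the Gapdh covariate (adjusted p = 0.212). Of 6 cuticle and lipid-transfer genes 1 fell, also adjusted over the list alone, with a median of -0.71 (camera adjusted p = 0.000224; adjusted p = 0.0136 with an estimated correlation). That gene was LTP110-A at -1.22 (SE 0.239, adjusted p = 0.007). In single joints EXPA1, IAA30 and IAA12 were called in the second and the third and not in the last (-1.08, -0.95 and -1.13, adjusted p = 0.765, 0.485 and 0.395), EXPB6 and LTP110-A in the third alone and IAA6 in the second alone. Of these 6, the interaction was called for EXPB6 alone (adjusted p = 0.0173). The calls of the Aux/IAA and the cuticle lists were the 2 of 46 that held with an estimated correlation. None of 23 ribosomal protein genes was called by limma, with 14 lower and 0 higher at an unadjusted p under 0.05 and a median of -0.20 (camera adjusted p = 5.67e-05; adjusted p = 0.891 with an estimated correlation). Of 10 tubulins 1 fell, also adjusted over the list alone, TUB6 at -1.18 (in single joints called in the last alone), with a median of -0.20 (camera adjusted p = 0.0227). Of 5 primary wall cellulose synthases none was called, 3 being lower at an unadjusted p under 0.05 with a median of -0.45 (camera adjusted p = 0.0383; adjusted p = 0.891 with an estimated correlation for both lists). The tubulin list lost its call without the last joint at stage 6 replicate 1 (0.0506), the second joint at stage 5 replicate 2 (0.0798), the third joint at stage 5 replicate 2 (0.0649) or the third joint at stage 6 replicate 1 (0.271), and with the mean of a gene's probe sets (0.0705). The primary wall list lost its call without replicate 1 of the last joint at stage 5 (0.072) or stage 6 (0.0687), replicate 2 of the second joint at stage 5 (0.167) or stage 6 (0.0818), the third joint at stage 5 replicate 2 (0.0649) or the third joint at stage 6 replicate 1 (0.141). It also lost it after a further quantile normalisation (0.0505) or without dim probe sets (0.0525). With fry the ribosomal (0.0966), tubulin (0.096) and primary wall (0.127) lists were not called. The Gapdh difference rose from 1.87 to 3.27 in the second joint and from 1.94 to 3.17 in the third, and was 3.13 and 3.18 in the last. With it as a covariate the expansin, tubulin and primary wall lists had camera adjusted p = 0.474, 0.326 and 0.778, LTP110-A 0.159, and 357 probe sets were called.

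Of 43 heat-shock genes 4 rose at the same step and 0 fell, also adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.0383; adjusted p = 0.891 with an estimated correlation). HSP24.1 rose by 2.22 (SE 0.36, adjusted p = 0.0018) and HSP18.0/HSP18.1 by 1.91 (SE 0.204, adjusted p = 6.87e-05). In single joints HSP18.0/HSP18.1 was called in all 3. HSP24.1 was called in the second alone, at 4.90 (adjusted p = 0.000722). It was 1.20 in the last (adjusted p = 0.843) and 0.57 in the third (adjusted p = 0.854; interaction adjusted p = 0.00368). Its level in the second joint was 9.02 at stage 4, 5.92 at stage 5 and 10.8 at stage 6. The arrays of the second joint at stage 5 correlate least of all replicates (r = 0.971), which limits calls in that joint alone. The list lost its call without replicate 2 of the last joint at stage 5 (0.119) or stage 6 (0.0508), replicate 2 of the second joint at stage 5 (0.192) or stage 6 (0.0649), the third joint at stage 5 replicate 2 (0.0649) or the third joint at stage 6 replicate 1 (0.325). It also lost it without dim probe sets (0.0727). The metallothionein MT1B rose by 2.43 (SE 0.247, adjusted p = 4.06e-05), the transcription factor NAC010 by 2.11 (SE 0.291, adjusted p = 0.000529), and of the lipid oxidation genes LOX8 by 2.49 (SE 0.451, adjusted p = 0.00405) and OPR1/OPR2 by 2.33 (SE 0.571, adjusted p = 0.0248). Pi21, a protein of a blast resistance locus, fell by 2.74 (SE 0.284, adjusted p = 4.68e-05), the phytosulfokine precursor PSK2 at -2.38 (SE 0.461, adjusted p = 0.0065), CPS (LOC4329013) at -1.89 (SE 0.307, adjusted p = 0.00185) and NAS1 at -2.94 (SE 0.814, adjusted p = 0.0449). In single joints MT1B, NAC010 and Pi21 were called in the second and the third and not in the last (1.95, 0.80 and -1.75, adjusted p = 0.11, 0.943 and 0.271). LOX8 was called in the second alone, at 4.61 (adjusted p = 0.00405), with 0.40 in the last and 2.45 in the third (interaction adjusted p = 0.108). OPR1/OPR2 and PSK2 were also called in the second alone, and CPS and NAS1 in no single joint. Of these 8 genes the interaction was called for Pi21 alone (adjusted p = 0.0136). Leaving out 1 array moved OPR1/OPR2 to between 1.78 and 2.88 and NAS1 to between -3.63 and -2.25. Each lost its call in 8 of these 12 fits. With the Gapdh covariate, LOX8 (0.0508), OPR1/OPR2 (0.0677), PSK2 (0.0753), CPS (0.094) and NAS1 (0.445) lost their calls. NAS1 also lost its call with only the arrays compared (0.0972) and with both doubtful arrays out (0.105). None of 5 senescence genes was called by limma, with 1 higher and 1 lower at an unadjusted p under 0.05 (median 0.02, camera adjusted p = 0.915). SGR was at 0.26 and NYC1 at -0.11, and LG1 at 0.52, SLR1 at 0.41 and BU1 at -0.48 were not called. LG1 was at 0.86 (adjusted p = 0.0204, under the fold limit) and 0.17 without replicates 1 and 2 of the third joint at stage 6, where SGR was at 0.11 and 0.40. BU1 was at -0.75 and -0.22 without replicates 1 and 2 of the second joint at stage 5. The light-harvesting and KNOX lists had 0 genes called, with 2 and 5 at an unadjusted p under 0.05, and the floral MADS list 1 higher of 8 (median -0.09, mean 0.02). The count of 994 (51.8% higher) was 1627 (61.9%) without the third joint at stage 6 replicate 1 and 652 (45.9%) without its replicate 2. Of the 994, 940 (94.6%) moved the same way in all 3 positions, and r across genes was 0.513 between the last and the second joint, 0.185 between the last and the third and 0.257 between the second and the third. Without the third joint at stage 6 replicate 1 the last 2 were 0.271 and 0.446, without its replicate 2 they were 0.0185 and -0.062, and without the last joint at stage 5 replicate 1 the first of them was 0.0907.

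**Figure D5:**
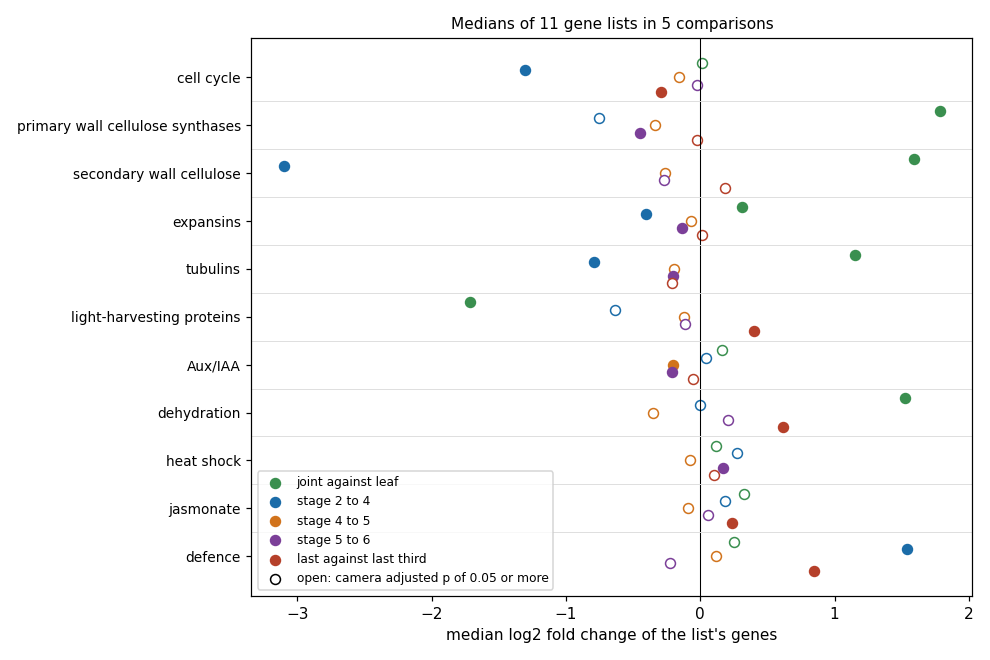
Median log2 fold change (horizontal axis) of the genes of 11 lists in 5 comparisons, with filled points where the camera adjusted p is under 0.05 and open points otherwise. Secondary wall cellulose genes have a median of 1.59 in the joint against the leaf and of -3.10 from stage 2 to stage 4.

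Leaf positions were compared over the 4 stages, 8 arrays against 8. Position is tied to harvest day and cannot be told from it. Between the last and the third joint, 430 probe sets were higher in the last joint and 223 lower. At an adjusted p under 0.05 alone, 1369 were higher and 1663 lower, so the balance turns. Of 15 defence genes 7 were called higher in the last joint and 0 lower, also adjusted over the list alone, with a median of 0.85 (camera adjusted p = 5.55e-06; adjusted p = 0.491 with an estimated correlation). PBZ1, a pathogenesis-related protein, was higher by 2.34 (SE 0.197, limma adjusted p = 1.34e-05) and Cht11 by 1.86 (SE 0.193, adjusted p = 0.000102). Both averages rest on stage 2, where PBZ1 differed by 6.63 (adjusted p = 4.76e-08) and Cht11 by 5.74 (adjusted p = 1.23e-07). At stages 4, 5 and 6 neither was called, with PBZ1 at 0.72, 0.59 and 1.41 and Cht11 at -0.15, 1.08 and 0.75 (adjusted p from 0.136 to 0.968). The largest differences were those of the flowering genes MADS34 at 6.01 (SE 0.319, adjusted p = 7.51e-08) and MADS15 at 3.87 (SE 0.434, adjusted p = 0.000151), PBZ1, MADS14 at 2.09 (SE 0.338, adjusted p = 0.00198) and the peroxygenase PXG at 2.02 (SE 0.481, adjusted p = 0.0218). In the other direction were the aquaporin PIP2-5 at -1.58 (SE 0.282, adjusted p = 0.00399), MADS47 at -1.36 (SE 0.107, adjusted p = 7.88e-06), PHO1-2 at -1.31, PLA2-III at -1.25 and MADS50 at -1.20. By stage, MADS34 was called at all 4, MADS47 at stages 2, 4 and 5, MADS15 at stages 2 and 4, and PIP2-5, PLA2-III and MADS50 at stages 4 and 5. MADS14 was called at stage 4 alone (adjusted p = 0.0272, with 0.0512, 0.357 and 0.622 at stages 2, 5 and 6), PXG at stage 2 alone (3.94) and PHO1-2 at stage 5 alone (-3.06). Of 32 jasmonate genes 3 were called higher and 4 adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.00967; adjusted p = 0.544 with an estimated correlation). LOX9 at 1.31 and OPR4/OPR6 at 1.20 are among them, the first called at no single stage and the second at stage 6 alone (2.43). Of 8 dehydration genes 1 was higher, also adjusted over the list alone, rDRP1 at 1.20 (adjusted p = 0.0257), with a median of 0.61 (camera adjusted p = 0.0256; adjusted p = 0.544 with an estimated correlation). The average of rDRP1 rests on stage 2, at 3.38 (adjusted p = 0.00145), and it was not called at stages 4, 5 and 6, with 0.35 and 1.05 at the last 2 of these (interaction adjusted p = 0.0744). PXG lost its call without the last joint at stage 2 replicate 2, stage 4 replicate 2 or stage 6 replicate 1, without the third joint at stage 4 replicate 2 or stage 5 replicate 2 (adjusted p up to 0.0635), and with both doubtful arrays out (0.0503). Leaving out 1 of the 16 arrays moved rDRP1 to between 1.02 and 1.37. Its call was lost in 10 of these 16 fits. OPR4/OPR6 was at 0.95 without the third joint at stage 4 replicate 2. The dehydration list lost its call without the last joint at stage 2 replicate 2 (0.0692) or stage 5 replicate 1 (0.0551), or the third joint at stage 2 replicate 1 (0.054), stage 4 replicate 2 (0.0631) or stage 6 replicate 2 (0.0794). It also lost it with both doubtful arrays out (0.0716), with fry (0.0904) and with the mean of a gene's probe sets (0.144).

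Other lists differed between the last and the third joint in camera with 0 genes called by limma. They were lower for ribosomal proteins (10 of 23 lower at an unadjusted p under 0.05, median -0.17, camera adjusted p = 0.00512), DNA replication (10 of 28, median -0.23, 0.0102) and the cell cycle (6 of 26 with 3 higher, median -0.29, 0.0241). They were higher for lignin (8 of 29 higher, median 0.25, 0.0241) and light harvesting (3 of 7 higher, median 0.40, 0.0265). With an estimated correlation their adjusted p were 0.544, and 0.621 for the ribosomal proteins. The ribosomal list lost its call without the third joint at stage 2 replicate 2 (0.145), and the lignin list without the third joint at stage 4 replicate 2 (0.0584) and with both doubtful arrays out (0.0716). The cell cycle list lost it without the last joint at stage 2 replicate 2 (0.0873) or stage 4 replicate 1 (0.0552), or the third joint at stage 2 replicate 2 (0.168), stage 4 replicate 1 (0.052) or stage 6 replicate 2 (0.0518). Without dim probe sets it lost it as well (0.108), as the DNA replication list did (0.199). With fry the ribosomal (0.11), DNA replication (0.102), cell cycle (0.102) and light-harvesting (0.0636) lists were not called. The light-harvesting list lost it without the last joint at stage 5 replicate 1 (0.0622), or the third joint at stage 2 replicate 2 (0.0561), stage 4 replicate 1 (0.053), stage 5 replicate 2 (0.11) or stage 6 replicate 2 (0.115). The cuticle, KNOX and floral MADS lists had 0 genes called by limma, with 2, 1 and 4 at an unadjusted p under 0.05 and medians of -0.05, 0.04 and 0.15. GSK2 at -0.87 (adjusted p = 0.0214) and LIC at -0.40 (adjusted p = 0.049) were under the fold limit, and GSK2 reached it without the third joint at stage 4 replicate 1 (-1.01) and, by little, with the Gapdh covariate. BU1 at 0.87 (adjusted p = 0.063) was called, just at the limit, without the last joint at stage 2 replicate 1, and LG1 at 0.36 was not called (0.10 and 0.62 without replicates 1 and 2 of the third joint at stage 6).

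Between the last and the second joint, 78 probe sets were higher in the last joint and 30 lower. Of 7 light-harvesting genes 1 was called higher, also adjusted over the list alone, with a median of 0.70 (camera adjusted p = 1.84e-05; adjusted p = 0.462 with an estimated correlation). That gene was RCABP69 at 1.15 (adjusted p = 0.0138), just under the fold limit without the second joint at stage 6 replicate 1 and at adjusted p = 0.0527 with the Gapdh covariate. Of 15 defence genes 1 was called higher, Rcb4 at 1.14 (adjusted p = 0.00881), and 2 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.0424; adjusted p = 0.651 with an estimated correlation). Both genes are named after their values were seen. By stage RCABP69 was called at none (adjusted p of 0.0704 or more) and Rcb4 at stage 5 alone (1.94, adjusted p = 0.0221). The cell cycle (median -0.30, 0.00111), jasmonate (-0.17, 0.011), tubulin (-0.19, 0.0114), primary wall (-0.29, 0.0292) and DNA replication (-0.07, 0.0292) lists were lower with 0 genes called by limma, and 8, 3, 3, 2 and 4 genes lower at an unadjusted p under 0.05. With an estimated correlation the adjusted p of these 5 lists lay between 0.535 and 0.705. The jasmonate list lost its call without the second joint at stage 5 replicate 2 (0.0801), and the tubulin list without that array (0.0517), the last joint at stage 4 replicate 1 (0.0611) or the second joint at stage 2 replicate 2 (0.0961). The primary wall list lost it without the last joint at stage 2 replicate 1 (0.0648), stage 4 replicate 1 (0.0758) or stage 5 replicate 2 (0.0673), or the second joint at stage 5 replicate 2 (0.14) or stage 6 replicate 1 (0.0519). The DNA replication list lost it without the last joint at stage 2 replicate 2 (0.122) or stage 5 replicate 1 (0.0556), or replicate 2 of the second joint at stage 2 (0.217) or stage 5 (0.14). The defence list lost it without the last joint at stage 2 replicate 1 (0.255), without replicate 2 of the last joint at stages 4, 5 or 6 (0.111, 0.0751 and 0.0639), and without replicate 2 of the second joint at stages 2, 4, 5 or 6 (0.36, 0.125, 0.14 and 0.182). With fry the light-harvesting list alone was called, with adjusted p = 0.275 for the cell cycle, tubulin and defence lists, 0.33 for jasmonate and primary wall and 0.612 for DNA replication. The mean of the cell cycle list was -0.16 without the last joint at stage 2 replicate 2, in place of -0.25. Calls were also lost without dim probe sets (cell cycle 0.0516, DNA replication 0.569), with only the arrays compared (defence 0.0903) and with the Gapdh covariate (primary wall 0.212, jasmonate 0.0852). The count of 108 (72.2% higher) was 191 without replicate 1 of the last joint at stage 2 (47.1%) or stage 4 (67.5%) and 226 (75.7%) without the second joint at stage 5 replicate 2. It was 65 without the last joint at stage 2 replicate 2, 68 without its stage 5 replicate 2, 67 without its stage 6 replicate 1, 68 without the second joint at stage 4 replicate 1 and 62 without its stage 6 replicate 1.

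Between the second and the third joint, 149 probe sets were higher in the second joint and 66 lower, and with no fold limit 392 were higher and 669 lower, again the other balance. Of 32 jasmonate genes 1 was called higher and 4 adjusted over the list alone, with 17 higher and 1 lower at an unadjusted p under 0.05 and a median of 0.43 (camera adjusted p = 1.02e-08; adjusted p = 0.202 with an estimated correlation). Of 15 defence genes 3 were higher (median 0.23, camera adjusted p = 0.000151; adjusted p = 0.44 with an estimated correlation) and of 29 lignin genes 2 (median 0.20, camera adjusted p = 0.00171; adjusted p = 0.431 with an estimated correlation), with the same counts adjusted over the list alone. The jasmonate gene was TIFY11C at 1.46 (adjusted p = 0.00146), the defence genes PBZ1 at 1.89 (adjusted p = 0.000241), Cht11 at 1.45 (adjusted p = 0.00146) and Cht2/Cht8 at 1.07 (adjusted p = 0.016), and the lignin genes ZB8 at 1.25 (adjusted p = 0.0236) and 4CL5 at 1.56 (adjusted p = 0.0132). These genes are named after their values were seen. All 6 averages rest on stage 2, where TIFY11C differed by 5.32, PBZ1 by 5.78, Cht11 by 5.06, Cht2/Cht8 by 5.19, ZB8 by 3.76 and 4CL5 by 5.97 (adjusted p up to 0.000214). None was called at stages 4, 5 or 6 (adjusted p of 0.119 or more), with Cht2/Cht8 at -1.62 at stage 4. Cht2/Cht8 lost its call without replicate 1 of the second joint at stage 2 (0.94), stage 4 (0.98) or stage 6 (adjusted p = 0.0581), or the third joint at stage 5 replicate 2 (0.0522). ZB8 lost its call without replicate 1 of the second joint at stage 2, 4 or 6, its stage 4 replicate 2, the third joint at stage 4 replicate 2 or either stage 5 array of the third joint (adjusted p up to 0.0769), and 4CL5 without the second joint at stage 6 replicate 1 (0.0502). None of 8 dehydration genes was called by limma, 3 being higher at an unadjusted p under 0.05 (median 0.61, 0.00162), and none of 23 ribosomal protein genes, 6 being lower (median -0.15, 0.00238). With an estimated correlation the adjusted p of these lists were 0.446 and 0.61. With fry the ribosomal (0.15), dehydration (0.0825) and lignin (0.0607) lists were not called. The ribosomal list lost its call without the third joint at stage 2 replicate 2 (0.236). The dehydration list lost it with both doubtful arrays out (0.0607), and its mean was 0.36 without the second joint at stage 2 replicate 1, in place of 0.65. The count of 215 was 118 and 395 without replicates 1 and 2 of the second joint at stage 2, 130 and 142 without those of its stage 4, 389 without its stage 5 replicate 1 and 115 without its stage 6 replicate 1. It was 334 without the third joint at stage 4 replicate 1, 136 without its stage 5 replicate 2, and 106 with only the arrays compared.

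Whether a stage step differed between leaf positions was asked of each probe set by limma's F-test, and 3139 of 57258 (5.48%) had an adjusted p under 0.05. By step, 2742 differed from stage 2 to stage 4, 1379 from stage 4 to stage 5 and 215 from stage 5 to stage 6. PBZ1 rose from stage 2 to stage 4 by 6.16 in the third joint, against 0.25 in the last and 0.99 in the second (interaction adjusted p = 4.01e-05). At stage 2 its level was 6.84 ± 0.17 (SD, n = 2 arrays) in the third joint, and 13.5 and 12.6 in the last and the second. Cht11 rose by 8.62 in the third joint against 2.74 and 3.19 (interaction adjusted p = 6.72e-05). SGR, which acts in chlorophyll breakdown, changed by 1.62 in the third joint and by -0.64 and -0.31 in the last and the second (interaction adjusted p = 0.00217). MADS34 changed by 4.49 in the second joint, 1.12 in the last and 0.30 in the third (interaction adjusted p = 0.0355). From stage 4 to stage 5, HSP24.1 changed by 2.96 in the last joint, -3.11 in the second and 1.85 in the third (interaction adjusted p = 0.00368). The Gapdh difference at stage 2 was 1.47 on both arrays of the third joint and 1.93 to 2.09 on those of the last and the second. With the Gapdh covariate 1225 probe sets differed from stage 2 to stage 4, 1033 of them among the 2742. The count of 3139 was 8232 without the second joint at stage 5 replicate 2, 1973 and 2043 without replicates 1 and 2 of the second joint at stage 4, and 1965 and 1974 without replicates 1 and 2 of the third joint at stage 5.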

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

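The test of weaker 5′ signal as the whole cause of the change from stage 5 to stage 6 was chosen only after the result was seen, the alternatives with the Gapdh covariate or without the 2 doubtful arrays were added after seeing the data, and the limits for reading the tests of the whole cause, the doubtful arrays, leaf tissue, unequal 5′ signal at stage 2 and other splits where the real one calls 0 were tightened after their values were seen. The counts for the stage 2 to stage 4 step alone with the covariate and the correlations within positions over probe sets with little joint to leaf difference were also added then.

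A test of the difference itself, limma's F-test, called 3139 probe sets whose stage step differs between leaf positions: 2742 from stage 2 to stage 4, 1379 from stage 4 to stage 5 and 215 from stage 5 to stage 6. Of the 96 genes named by the rule, called or not, 19 have such a difference. Defence genes have the lowest interaction adjusted p, PBZ1 4.01e-05, Cht11 6.72e-05 and Cht2/Cht8 8.44e-05. The wall genes are EXPB11 (0.0125), EXPB6 (0.0173), EXPA6 (0.0216), GLU8 (0.0315) and EXLA4 (0.0362), and the flowering genes MADS15 (0.0306) and MADS34 (0.0355). The others are SGR (0.00217), HSP24.1 (0.00368), Pi21 (0.0136), PIP2-5 (0.0182), MCM4 (0.0216), GH3.8 (0.0323), LA (0.0356), PLA2-III (0.0386) and D11 (0.0491).

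In the Gapdh control probe sets, which the comparisons do not use, 9 arrays exceed the higher leaf array by more than 1 in the 3′ minus 5′ difference, and the highest value is 3.78 in the third joint at stage 4 replicate 2.

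The first pattern is the change from stage 5 to stage 6, where the Gapdh difference rises in the second and the third joint and not in the last, which had 3.13 and 3.18. The last joint therefore tests whether weaker 5′ signal is the whole cause. Over the 1289 probe sets called in the other positions, its median change in the same direction was 0.63, against 1.39 there, or 45.7% (50.7% and 37.9% by replicate), and 88.5% moved the same way, which argues against the whole cause. Whether it is part of the cause stays open. The pair of replicates that differs most in it, the third joint at stage 4, had a median signed difference of -0.0066 with quartiles of -0.44 and 0.49, and a single pair cannot exclude it. Senescence, which the stage labels name, is untested as the remainder.

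The second pattern is that stage 4 to stage 5 steps of separate positions do not move together across genes. Steps from separate arrays of 1 position correlate at a mean r of 0.424, which argues against replicate noise. Differing amounts of leaf in the cut joints stay open. Over 33010 probe sets with little joint to leaf difference the mean r was -0.0436 (SD 0.102), under the preset bound of 0.1. That bound was wrong, as these were chosen with arrays of the pattern and 64.3% are dim. Steps within positions repeat over them at mean r 0.275 (11796 not dim 0.393, against -0.0649 between positions). Leaf was measured in 1 position at 1 stage. The 2 doubtful arrays stay open (mean r without them 0.0642, SD 0.0736 over the 3 pairs). Unequal 5′ signal stays open. The Gapdh difference rises in the last joint alone and falls in the third, from 2.86 to 1.94. Calls in the last joint go from 453 to 15 with the covariate, which cannot decide this. Its slope rests mainly on the 2 arrays of the third joint at stage 4, and a Gapdh difference between groups also widens the SE. Harvest day, tied to position, is untested.

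The third pattern is that more probe sets are called from stage 2 to stage 4 in the third joint (8303, and 6397 to 8871 without 1 array) than in the last (5201) or the second (6221), although over the 6093 called in the mean of the last and the second its median step was 1.66 against 1.61 there. An earlier point of development at stage 2 stays open, because over these it lay a median of 0.126 further from stage 4 than the other joints, with quartiles of -0.34 and 0.64, and 57.9% lay further. Unequal 5′ signal stays open too. With the Gapdh covariate the interaction count over all steps was 2439, or 77.7% of 3139 in number, with 2106 in both, which would meet the bound set beforehand against this cause, but that bound was wrong in covering all steps, as for stage 2 to stage 4 the count was 1225 against 2742, with 1033 in both. Over the 2839 probe sets whose step in the third joint differs from the mean of the others, the median difference was 1.72 before and 1.52 after and the median SE 0.350 and 0.440, so calls ended through both.

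Other splits of the arrays into groups of the same sizes were fitted with 2 groups and a block for position or stage, which is not the fit of the report and calls fewer probe sets. Out of 100 splits, the real one alone called as many for stage 2 to stage 4 (6153, highest other 1946) and stage 4 to stage 5 (164, highest other 124). The same held for the last against the third joint (282, highest other 1) and the last against the second (48, highest other 0). These splits moved single arrays, so they cannot exclude chance differences shared by the 2 arrays of a group. For stage 5 to stage 6, 2 of 100 splits called as many, the real one with 568 and 1 other with 1042, so the real one does not stand out. The other split keeps 10 of the 12 arrays on their side and differs more in the Gapdh value, by just over 1 against 0.897. For the second against the third joint this decides nothing, as the real split called 0, so all 100 splits have as many (highest other 23).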

How the results depend on the processing

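The alternatives with the Gapdh covariate, without both doubtful arrays, and all those within positions or for step correlations were added after seeing the data, and where no cause is given below the cause was not tested. No called gene or list reversed its direction, but balances of higher and lower calls and signs of step correlations did. Quantile normalisation, median centring, no dim probe sets, and trend with robust fitting kept every count within 1.5 times. Median centring and trend with robust fitting also kept all 46 list calls, dim probe sets left out kept 37 and quantile normalisation 44. In the second joint alone, quantile normalisation moved the share of higher calls from 29.6% to 43.4% from stage 4 to stage 5 and from 71.8% to 55% from stage 5 to stage 6. Without the second joint at stage 5 replicate 1 these shares were 66.1% and 33.8%, and without both doubtful arrays 68.4% and 31.1%. Of 212 entries for named and additional genes, none changed its call with quantile normalisation or median centring, nor did any of the 198 left to test without dim probe sets. Without both doubtful arrays 9 lost and 1 gained a call, with only the arrays compared 21 lost it, and with the Gapdh covariate 16 lost and 2 gained it. An estimated correlation kept 2 list calls, fry 29 (its 17 losses lie from stage 5 to stage 6 and between positions), the covariate 39 and both doubtful arrays out 42.

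With 1 probe set per gene, which tests fewer probe sets, counts were 2720 for joint against leaf (54.5% higher, in place of 46.1%), 4013 for stage 2 to stage 4, 131 for the second against the third joint and 1855 for the interaction. With only the arrays compared, which leaves fewer degrees of freedom, joint against leaf gave 2118 (60.2% higher) and the second against the third joint 106. With no fold limit, counts were 16770, 728 and 3093 for the 3 stage steps in order, and 3032 (45.2% higher, in place of 65.8%), 414 (77.3%) and 1061 (36.9%, in place of 69.3%) for the last against the third, the last against the second and the second against the third joint. With treat, a stricter test of the same limit, they were 2867, 14 and 23 for the steps, 761 for joint against leaf, and 6, 0 and 0 for the position pairs. Neither was run for the interaction, which has no fold limit.

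With the Gapdh covariate, stage 5 to stage 6 gave 357, of which 230 are among the 994. The median fold of the 994 was 1.32 before and 1.33 after, and the median SE grew from 0.259 to 0.381. Single folds may also have moved. Within positions it gave 15 for the last joint (453) and 165 for the third (432) from stage 4 to stage 5, and 1066 for the second (2250) and 53 for the third (589) from stage 5 to stage 6. Without both doubtful arrays, the step from stage 4 to stage 5 gave 737 in the last, 209 in the second and 258 in the third joint, and stage 5 to stage 6 gave 761 in the second and 941 in the third.

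Step correlations that changed sign when 1 array was left out were those from stage 4 to stage 5 in all 3 pairs and that of the second with the third joint from stage 5 to stage 6 (0.257, and -0.062 without the third joint at stage 6 replicate 2). Leaving out 1 array leaves a group with 1, assumed to vary like the others. Counts then ran from 3067 to 4292 for joint against leaf, 6109 to 7016, 243 to 720 and 652 to 1627 for the steps, 460 to 973, 62 to 226 and 115 to 395 for the position pairs, and 1965 to 8232 for the interaction. Within the last joint they ran from 3577 to 4811, 49 to 303 and 15 to 38 (of 5201, 453 and 80), within the second from 4374 to 5342, 94 to 4965 and 341 to 6407 (of 6221, 739 and 2250), and within the third from 6397 to 8871, 43 to 773 and 78 to 818 (of 8303, 432 and 589). The same-stage distance ran from 0.450 to 0.490, list calls from 37 to 49 and calls of named genes from 84 to 97.

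The labels do not say whether replicate numbers pair the samples, and the fit does not pair them. Over 78 pairs of groups, deviations of equal numbers correlated at r from -0.306 to 0.553 (median 0.0397, 24 above 0.1 and 12 below -0.1). The best match of 20 of 26 arrays had their own number, but the 2 deviations of a group mirror each other, so this counts 10 of 13 groups, a hint from the data and not from the design. With the replicate number as a block, counts were 4333 for joint against leaf, 6583, 413 and 1034 for the steps, 681, 138 and 240 for the position pairs, and 3525 for the interaction. With the block there were 47 list calls and 96 named gene calls, and none was lost.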

Other observations

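The genes below were chosen after their values were seen. From stage 2 to stage 4 the sugar transporters MST3 rose by 4.45 (SE 0.241, limma adjusted p = 3.97e-10) and SWEET14 by 3.06 (SE 0.206, adjusted p = 5.5e-09), and the aquaporin PIP2-7 rose by 4.47 (SE 0.271, adjusted p = 1.53e-09). The aquaporin NIP1-1 fell by 3.54 (SE 0.149, adjusted p = 2.01e-11). The cytokinin-activating LOGL9 rose by 4.22 (SE 0.206, adjusted p = 1.15e-10) and LOGL3 by 2.77, and the jasmonate synthesis genes LOX9 and AOS2 were at 2.88 and 2.75. Among growth genes, SPL18 fell by 3.36 (SE 0.178, adjusted p = 3.13e-10), and IPA1, MCM7 and RPA2A were at -2.59, -2.30 and -2.51 (RPA2A at -0.79, not called, in the last joint alone). These calls held whichever array was left out. Their lists as wholes were not called by camera at this step: cytokinin at adjusted p = 0.382, jasmonate 0.491, sugar transport 0.432, aquaporins 0.167, growth-regulating factors 0.109 and DNA replication 0.282.

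In the joint against the leaf, IAA31 and IAA30 were higher by 3.61 (SE 0.308, adjusted p = 1.14e-06) and 3.06 (SE 0.328, adjusted p = 1.18e-05), and IAA8 differed by -2.13. The kinesins KIN5A and KIN14C were at 2.68 and 2.64, and the aquaporins PIP2-5, NIP1-1 and PIP2-7 at 3.43, 2.74 and -3.11. These calls held whichever array was left out. From stage 5 to stage 6 the jasmonate gene OPR4/OPR6 rose by 1.87 (SE 0.268, adjusted p = 0.000706) and the expansin EXPA7 fell by 1.80 (SE 0.247, adjusted p = 0.000501). In single joints OPR4/OPR6 was called in the second alone and EXPA7 in the second and the third. EXPA7 was not called with the Gapdh covariate (adjusted p = 0.0902).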
